A study of Mus musculus with 35 samples.

How the data were processed

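RNA of whole mouse testis was measured on Affymetrix mouse arrays, 1 array type at postnatal day 15 (18 arrays) and another at day 25 (17 arrays). The groups cross Akt1 genotype (wild type, heterozygous, homozygous mutant) with exposure to propylthiouracil (PTU) or none. Another exposed homozygous array of day 25 was left out by the authors as of poor quality, per the design text, and is not analysed here. The values are log2 intensities from RMA, deposited by the authors per the labels; the version of RMA is not given in the sources used here. The values were used as deposited, after a check that they lie on a log2 scale (2.19 to 14.9 at day 15, 2.81 to 15.1 at day 25).

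Probe sets were joined to gene symbols by the annotation of each array type. At day 15, of 35556 probe sets 21789 have 1 symbol, 1621 several and 12146 none; at day 25, of 45101, the numbers are 34958, 932 and 9211. Only probe sets with 1 symbol entered, and the probe set with the highest mean stood for its gene. Genes above the 25th percentile of all values (5.56 at day 15, 4.76 at day 25) in at least 2 arrays were tested: 16710 of 19938 and 16305 of 18194.

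Each age was fitted by itself in R 4.3.3 with limma 3.58.1: lmFit on the 6 group means, contrasts.fit and eBayes with default settings, and Benjamini-Hochberg adjustment with a threshold of 0.05 in each contrast. There are 10 contrasts per age: the PTU effect in each genotype and averaged over genotypes, homozygous minus wild type in unexposed, in exposed and averaged, heterozygous minus wild type averaged, and the interaction of PTU with the homozygous and with the heterozygous genotype. Standard errors are limma's moderated ones. Gene lists were written from general knowledge of testis cell types and pathways. They were tested with camera (preset correlation 0.01), adjusted over the 25 lists of a contrast, with at least 3 members; members past the threshold were also counted after adjustment over the list alone. A list mean is the average of its tested members' values in an array. Effects of 2 contrasts were compared across genes by Pearson and Spearman correlation and by counts of shared genes against the product of their shares.

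Genes are named by rule: the targeted gene and its relative; up to 10 largest rises and falls among passing genes whose arrays do not overlap between the groups compared; up to 4 list members with the smallest p; the 5 smallest p where fewer than 5 pass; and a fixed set of testis markers. With 3 arrays in each of 2 groups a gene without any effect shows no overlap in 10% of cases. The contrasts, lists, thresholds, naming rule and first set of alternatives were chosen before the data were examined.

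The fit was tested on simulated data with the group sizes of each age, with 50 genes changed by each of 0.3, 0.5, 1 and 2 log2. At day 15 (16710 genes) the PTU effect in wild type was found for 10%, 56%, 98% and 100% of them with 6 false calls, in homozygous mice for 4%, 36%, 98% and 98% with 4, averaged for 68%, 92%, 100% and 100% with 9, and the homozygous interaction for 2%, 12%, 84% and 98% with 7. At day 25 (16305 genes) the shares were 0%, 52%, 94% and 100% with 4 in wild type, 2%, 32%, 88% and 94% with 4 in homozygous mice, 62%, 86%, 100% and 100% with 7 averaged, and 0%, 8%, 70% and 100% with 2 for the interaction.

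Alternatives tried were no filter, a filter at the 50th percentile, every probe set on its own, quantile normalization, a fit on the groups compared alone, array weights, the sample number of the labels as a replicate block, leaving out each array in turn, camera with an estimated correlation, and fry. Chosen after the values were seen were array set at day 15 (from unnamed probe sets with a mean above 9) as a block or as a subset, the poly-A control mean or the 3' minus 5' difference of beta-actin as a covariate at day 25, a fit without the exposed homozygous arrays, and a fit without arrays in which Spink8 lies above 7. The labels give no litter, day or batch for the sample numbers, so pairing was judged from the residuals: the numbers pair the samples of a comparison where all of its 3 or more same-number correlations exceed 0.1. This held for PTU in heterozygous (0.391 to 0.444) and homozygous minus wild type exposed (0.141 to 0.557) at day 15, and for PTU in wild type at day 25 (0.233 to 0.396). To see how often a count arises by grouping alone, the labels of the arrays were exchanged between the groups of a contrast in all 10 ways or in 100 drawn ones, and each split was fitted in the same way.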

Results

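The study crosses Akt1 genotype (wild type, heterozygous, homozygous mutant) with propylthiouracil (PTU), a drug that blocks thyroid hormone synthesis, and reads RNA of whole mouse testis at 2 ages. At postnatal day 15 the first spermatocytes reach pachytene and Sertoli cells close the blood-testis barrier. By day 25 spermatids accumulate. There are 18 arrays at day 15 and 17 at day 25, with 3 per group except the exposed homozygous group at day 25, which has 2. The design text counts a separate mouse for every array, and nothing in the values shows whether the arrays of a group are separate animals as the labels say. The number of arrays limits precision: in simulated data 56% of the genes changed by 0.5 log2 were found for the PTU effect in wild type at day 15. The ages were measured on different array types, so each is tested only within itself. Gene values are log2 fold changes ± standard error from limma. An adjusted p is printed beside those above 0.01, and genes said to rise, fall or differ passed the test.

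Akt1 encodes the kinase that was targeted. At day 15 its transcript was lower in homozygous than in wild type testis over both exposures (-0.48 ± 0.15, adjusted p = 0.0283, 3 arrays per group). Within unexposed mice (-0.28 ± 0.22, adjusted p = 0.35) and within exposed mice (-0.68 ± 0.22, adjusted p = 0.101) the difference did not pass. The averaged call depends on settings. It has adjusted p = 0.0596 over every probe set instead of 1 per gene, and 0.0518 (-0.41) with quantile normalization. With array set (described below) as a block it has adjusted p = 0.0896 (-0.45), within the first set 0.442 (-0.22) and without the Spink8 arrays 0.295 (-0.32). Array weights give -0.82 (adjusted p = 0.0403) within exposed mice. At day 25 the brightest of 4 Akt1 probe sets gave -0.06 ± 0.06, adjusted p = 0.477. A dimmer probe set was lower by -0.79 ± 0.12 (adjusted p = 3.82e-04), and for heterozygous minus wild type it gave -0.36 ± 0.12 (adjusted p = 0.0592). The part of Akt1 that was deleted is not stated in the sources used here, so these values do not check the genotype labels. The related kinase gene Akt2 did not pass for homozygous minus wild type at day 15 (0.13 ± 0.05, adjusted p = 0.0817) or day 25 (-0.05 ± 0.06, adjusted p = 0.563). At day 15 it passes with quantile normalization (0.18, adjusted p = 0.0183) and array weights (0.18, adjusted p = 0.00985).

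The first question is how PTU alters the testis at day 15. Averaged over genotypes, Hsd17b3, which makes testosterone, rose (1.73 ± 0.17), and so did Akr1c14, a steroid reductase of immature Leydig cells (0.94 ± 0.11). Hsd3b6, a steroid dehydrogenase of adult Leydig cells, fell (-2.84 ± 0.37). Among genes of Sertoli cells and of transport to germ cells, Tsx fell (-2.02 ± 0.21), as did the carnitine enzyme Bbox1 (-2.17 ± 0.24). The water channel Aqp8 (-1.44 ± 0.13) and Emb, a partner of lactate transporters (-1.81 ± 0.19), fell too. The thyroid hormone targets Klf9 (-0.78 ± 0.14) and Hr (-0.28 ± 0.06) fell, while the receptor gene Thra rose (0.53 ± 0.12). The mean of 14 thyroid hormone action genes had no common direction over genotypes. With PTU it went from 7.70 to 7.78 in wild type, 7.85 to 7.78 in heterozygous and 7.92 to 7.78 in homozygous mice. Of 15 Leydig genes 3 rose, 2 fell and 10 did not pass (3 and 2 adjusted over the list alone). Their median was -0.02 (camera adjusted p = 0.769, adjusted p = 0.923 with an estimated correlation). The Leydig mean was -0.05 while camera's direction was up.

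**Figure D1:**
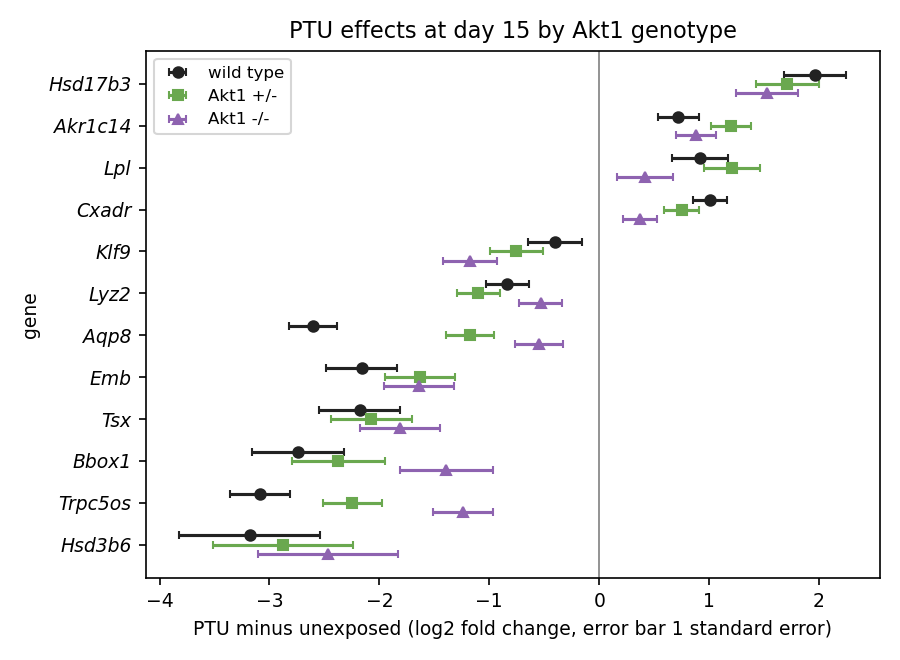
Log2 fold change under PTU at day 15 (x axis) for 12 genes (y axis) in each Akt1 genotype, 3 arrays per group, points with 1 standard error. Hsd17b3 lies at 1.96, 1.71 and 1.53 and Tsx at -2.18, -2.07 and -1.81 in wild type, heterozygous and homozygous mice.

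Macrophage transcripts fell with PTU at day 15. The lysosomal gene Cd68 (-0.54 ± 0.07), the mannose receptor Mrc1 (-0.77 ± 0.10), the growth factor receptor Csf1r (-0.47 ± 0.06) and the lysozyme gene Lyz2 (-0.82 ± 0.11) fell. Of 20 macrophage genes 0 rose, 13 fell and 7 did not pass (1 and 14 adjusted over the list alone). Their median was -0.43 (camera adjusted p = 3.18e-09, adjusted p = 0.126 with an estimated correlation). Genes that mark mature Sertoli cells fell as well: the iron carrier Trf (-0.47 ± 0.08), the protease Ctsl (-0.24 ± 0.05) and Shbg, which binds androgen (-0.62 ± 0.15, adjusted p = 0.0142). The tight junction gene Cldn11 also fell (-0.26 ± 0.07, adjusted p = 0.0222). Of 10 mature Sertoli genes 0 rose, 5 fell and 5 did not pass (0 and 7 adjusted over the list alone). Their median was -0.24 (camera adjusted p = 5.72e-04, adjusted p = 0.36 with an estimated correlation). Over all 16710 genes 649 rose and 1352 fell. Bright probe sets without a gene name divide the day 15 arrays into 2 sets that cross the groups, with every wild type array in the first. The count is 3650 with array weights, 2793 with array set as a block and 1028 within the first set, where Cldn11 (-0.18, adjusted p = 0.276) and Hr (-0.27, adjusted p = 0.0675) do not pass. Spink8, an epididymal transcript, reads 9.38 and 7.91 in unexposed wild type arrays 2 and 3 and 8.74 in exposed homozygous array 2. Without these arrays 846 genes pass, but not Thra (0.51, adjusted p = 0.069), Ctsl (-0.20, adjusted p = 0.0968) or Cldn11 (-0.21, adjusted p = 0.193), and without exposed wild type array 2 alone 1278.

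In wild type testis at day 15 PTU lowered genes of pachytene and later spermatocytes. The sperm surface gene Adam3 (-3.62 ± 0.41), the germ cell glycolysis gene Pgk2 (-2.27 ± 0.25), the meiotic cyclin Ccna1 (-0.95 ± 0.12) and the acrosome gene Spata16 (-2.48 ± 0.37) fell. Of 26 pachytene genes 0 rose, 15 fell and 11 did not pass (1 and 21 adjusted over the list alone). Their median was -1.21 (camera adjusted p = 8.15e-10, adjusted p = 0.578 with an estimated correlation). Of markers of immature Sertoli cells, Thra (1.08 ± 0.21), Amh (0.72 ± 0.23, adjusted p = 0.0454) and Ccnd2 (0.73 ± 0.17) rose. The tight junction gene Cldn3 fell (-0.57 ± 0.14) and the junction receptor Cxadr rose (1.01 ± 0.16). The signalling gene Dlk1 rose (1.30 ± 0.21), and the macrophage receptor Fcgr3 fell (-1.42 ± 0.24). Among 20 macrophage genes 0 rose, 10 fell and 10 did not pass (0 and 12 adjusted over the list alone). Their median was -0.40 (camera adjusted p = 5.46e-05, adjusted p = 0.578 with an estimated correlation). Over all genes 1091 rose and 1462 fell. Without the Spink8 arrays, which leaves 1 unexposed wild type array, 831 genes pass, but not Amh (0.81, adjusted p = 0.184), Ccnd2 (0.77, adjusted p = 0.0885) or Cldn3 (-0.34, adjusted p = 0.34). Amh also fails without the filter (0.72, adjusted p = 0.052) and with quantile normalization (0.67, adjusted p = 0.077). With array set as a block 3460 pass, within the first set 4389, with array weights 6820, and in a fit on these 2 groups alone 4370. Without a single array the count is 1182 (unexposed 1), 1535 (unexposed 3), 1116 (exposed 2) or 1195 (exposed 3).

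In heterozygous testis 32 genes rose and 63 fell with PTU at day 15. Hsd17b3 (1.71 ± 0.29), Akr1c14 (1.20 ± 0.18), the lipase Lpl (1.21 ± 0.26, adjusted p = 0.0411) and the Wnt inhibitor Sfrp1 (1.04 ± 0.15) rose. The phosphatase subunit Ppp2r2c (-1.63 ± 0.16), Trpc5os (-2.24 ± 0.27) and Bbox1 (-2.37 ± 0.42, adjusted p = 0.0137) fell. The macrophage genes Cd68 (-0.83 ± 0.12) and Lyz2 (-1.10 ± 0.20, adjusted p = 0.014) fell. In the macrophage list of 20 genes, 0 rose, 4 fell and 16 did not pass (0 and 12 adjusted over the list alone). Its median was -0.54 (camera adjusted p = 1.10e-10, adjusted p = 0.078 with an estimated correlation). Among 26 pachytene genes 0 rose, 0 fell and 26 did not pass (0 and 0 adjusted over the list alone). Their median was -0.47 (camera adjusted p = 0.00253, adjusted p = 0.767 with an estimated correlation). With array weights 499 genes pass, with array set as a block 104, within the first set 1, within the second 3, without the Spink8 arrays 48 and in a fit on these groups alone 31. Lpl does not pass in the block (adjusted p = 0.0611), without the Spink8 arrays (adjusted p = 0.0819) or on these groups alone (adjusted p = 0.0844), nor Lyz2 in that last fit (adjusted p = 0.0863). Leaving out unexposed array 1, 2 or 3 gives 41, 33 or 35, and exposed array 1, 2 or 3 gives 3, 47 or 414.

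In homozygous testis at day 15 PTU lowered Sertoli and junction genes. Tsx (-1.81 ± 0.37, adjusted p = 0.0111), Ctsl (-0.45 ± 0.09, adjusted p = 0.0132), the inhibin subunit Inha (-0.68 ± 0.14, adjusted p = 0.0142) and the growth factor receptor Erbb4 (-0.57 ± 0.13, adjusted p = 0.0177) fell. Of 28 Sertoli genes 0 rose, 7 fell and 21 did not pass (0 and 17 adjusted over the list alone). Their median was -0.33 (camera adjusted p = 2.26e-09, adjusted p = 0.298 with an estimated correlation). The kinase Fyn (-0.51 ± 0.09), the actin linker Vcl (-0.47 ± 0.09), the cadherin Cdh2 (-0.53 ± 0.11, adjusted p = 0.0131) and the tight junction gene Ocln (-0.65 ± 0.14, adjusted p = 0.0142) fell. Of 32 barrier genes 0 rose, 10 fell and 22 did not pass (1 and 14 adjusted over the list alone). Their median was -0.28 (camera adjusted p = 3.20e-05, adjusted p = 0.387 with an estimated correlation). Klf9 fell (-1.18 ± 0.24, adjusted p = 0.0122), Hsd17b3 rose (1.53 ± 0.29) and Hsd3b6 fell (-2.47 ± 0.64, adjusted p = 0.0346). Camera with its preset correlation called the spermatocyte lists up, but a rise is not established. Array means overlap in the pachytene list (7.01 to 7.63 unexposed, 7.46 to 8.37 exposed). They also overlap in the early meiotic list (9.82 to 10.13 unexposed, 10.08 to 10.61 exposed). In the pachytene list of 26 genes, 0 rose, 1 fell and 25 did not pass (8 and 1 adjusted over the list alone). Its median was 0.62 (camera adjusted p = 2.71e-05, adjusted p = 0.436 with an estimated correlation). Of 24 early meiotic genes 0 rose, 0 fell and 24 did not pass (9 and 0 adjusted over the list alone). Their median was 0.37 (camera adjusted p = 2.71e-05, adjusted p = 0.436 with an estimated correlation). Over all genes 98 rose and 730 fell. Limma on these 2 groups alone gives 0 genes (2695 at unadjusted p under 0.05), and on the arrays without Spink8 0 (2270). The first array set gives 0 (3993) with 1 exposed homozygous array, and the second set 4 with 1 unexposed homozygous array. Array weights give 1550, and the blocked fit by array set gives 836, without Hsd3b6 (-2.27, adjusted p = 0.0601). Leaving out unexposed array 1, 2 or 3 gives 91, 160 or 1283, and exposed array 1 or 2 gives 1598 or 56.

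The next question is how genotype alone alters the testis at day 15. Unexposed homozygous testes had less meiotic transcript than unexposed wild type testes, whose arrays also serve the PTU comparison in wild type. Adam3 (-4.38 ± 0.41), Pgk2 (-2.50 ± 0.25) and Tcp11 (-2.93 ± 0.34), genes of spermatocytes and sperm, were lower. Crisp2 (-5.29 ± 0.70), Ldhc (-4.72 ± 0.70) and Adam5 (-5.33 ± 0.74) were lower too. Of 26 pachytene genes 1 was higher, 20 lower and 5 did not pass (3 and 21 adjusted over the list alone). Their median was -2.12 (camera adjusted p = 2.34e-12, adjusted p = 0.449 with an estimated correlation). Of genes for synapsis and recombination, Syce1 (-1.20 ± 0.15), Spo11 (-1.58 ± 0.25) and Sycp3 (-0.57 ± 0.19, adjusted p = 0.029) were lower. Among 24 early meiotic genes 0 were higher, 17 lower and 7 did not pass (0 and 17 adjusted over the list alone). Their median was -0.77 (camera adjusted p = 4.19e-09, adjusted p = 0.449 with an estimated correlation).

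Sertoli cell, junction and spermatogonial genes were higher in the same unexposed homozygous testes. The RNA is of whole testis, so these values do not part a change within a cell type from a changed share of cell types. Amh, the hormone of immature Sertoli cells (1.39 ± 0.23), Thra (1.35 ± 0.21) and the stem cell factor Kitl (0.85 ± 0.13) were higher. Among 28 Sertoli genes 16 were higher, 1 lower and 11 did not pass (18 and 1 adjusted over the list alone). Their median was 0.35 (camera adjusted p = 1.27e-04, adjusted p = 0.449 with an estimated correlation). The junction genes F11r (0.70 ± 0.11), Ocln (0.58 ± 0.14) and Gja1 (0.49 ± 0.13) were higher and Nectin3 lower (-1.06 ± 0.13). Among 32 barrier genes 15 were higher, 2 lower and 15 did not pass (18 and 2 adjusted over the list alone). Their median was 0.27 (camera adjusted p = 7.49e-04, adjusted p = 0.449 with an estimated correlation). The stem cell genes Zbtb16 (0.83 ± 0.15) and Ret (0.74 ± 0.15) were higher and Id4 lower (-1.59 ± 0.30). Of 24 spermatogonia genes 11 were higher, 2 lower and 11 did not pass (14 and 2 adjusted over the list alone). Their median was 0.35 (camera adjusted p = 0.0129, adjusted p = 0.449 with an estimated correlation). Of 20 macrophage genes 1 was higher, 6 lower and 13 did not pass (1 and 7 adjusted over the list alone). Their median was -0.15 (camera adjusted p = 0.0453, adjusted p = 0.496 with an estimated correlation). Over all genes 2447 were higher and 2374 lower. Of 19 immediate early and heat shock genes 8 were higher, 1 lower and 10 did not pass (9 and 1 adjusted over the list alone). Their median was 0.19 (camera adjusted p = 0.0341, adjusted p = 0.496 with an estimated correlation). The fat transcript Car3 reads 8.57 and 6.87 in unexposed homozygous arrays 2 and 3, against 6.01 at most in unexposed wild type. Whether stress or fat in the sample bears on the meiotic genes was not tested. Blocked by array set 5591 pass, with array weights 7404, within the first set 6341, and without the Spink8 arrays 2476, where Sycp3 has adjusted p = 0.065 (0.0528 on these groups alone). Leaving out unexposed homozygous array 1 gives 3211 and unexposed wild type array 1 gives 3055.

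Among exposed mice at day 15, limma called 0 genes between homozygous and wild type, with 4266 at unadjusted p under 0.05. The smallest p belonged to the phosphatase Acp4 (0.56 ± 0.09, adjusted p = 0.0735), the viral restriction gene Fv1 (-0.71 ± 0.12, adjusted p = 0.0735) and the matrix gene Matn1 (0.62 ± 0.11, adjusted p = 0.0735), none past the threshold. Blocked by array set and within the first set limma also calls 0 (2260 and 1400 at unadjusted p under 0.05). With the sample number as a replicate block 750 genes pass, and Acp4, Fv1 and Matn1 then have adjusted p = 0.0305. Quantile normalization gives 123 genes (adjusted p = 0.0458 for these 3), array weights 1187 (adjusted p = 0.0244), and leaving out exposed homozygous array 1 gives 3308. Whether genes differ here thus depends on the setting. Averaged over exposure, 2242 genes were higher and 2479 lower in homozygous mice. The membrane gene Shisa6 was higher (0.85 ± 0.10) and Dmrtc1b lower (-1.10 ± 0.20). Among 26 pachytene genes 0 were higher, 20 lower and 6 did not pass (1 and 20 adjusted over the list alone). Their median was -1.13 (camera adjusted p = 6.40e-09, adjusted p = 0.716 with an estimated correlation). That gene count is 2991 with array set as a block, 1522 in the first set, 1719 without the Spink8 arrays, 2847 without exposed homozygous array 3 and 2633 without exposed wild type array 1.

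Between heterozygous and wild type mice at day 15, 21 genes were higher and 146 lower. The small GTPase gene Rasl2-9 (-1.06 ± 0.13), the sperm anion transporter Slc26a8 (-0.76 ± 0.15, adjusted p = 0.0179) and Ccna1 (-0.48 ± 0.08, adjusted p = 0.0107) were lower. The matrix gene Smoc2 was higher (0.44 ± 0.09, adjusted p = 0.0256). In the pachytene list of 26 genes, 0 were higher, 3 lower and 23 did not pass (0 and 8 adjusted over the list alone). Its median was -0.38 (camera adjusted p = 2.97e-05, adjusted p = 0.754 with an estimated correlation). Blocked by array set 34 genes pass, but not Slc26a8 (-0.73, adjusted p = 0.111) or Smoc2 (0.35, adjusted p = 0.162), and without the Spink8 arrays 93. Array weights give 1257. In the first set limma calls 0, with 1742 at unadjusted p under 0.05. Leaving out unexposed heterozygous array 1, 2 or 3 gives 452, 51 or 80, and exposed heterozygous array 2 gives 70. Leaving out unexposed wild type array 1 or 3 gives 44 or 79, and exposed wild type array 1 gives 57.

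Whether the PTU effect depends on Akt1 was tested by the interaction. At day 15 it was positive for the spermatocyte genes Pgk2 (2.59 ± 0.36), Adam3 (4.16 ± 0.58) and Ccna1 (1.11 ± 0.17) in homozygous mice. Of 26 pachytene genes 18 had a positive interaction, 1 a negative one and 7 did not pass (20 and 1 adjusted over the list alone). Their median was 2.04 (camera adjusted p = 3.30e-11, adjusted p = 0.438 with an estimated correlation). The mean of that list was 9.29 in unexposed and 8.05 in exposed wild type, 7.29 in unexposed and 7.97 in exposed homozygous mice. The interaction was negative for Amh (-1.07 ± 0.33, adjusted p = 0.0357), Thra (-1.01 ± 0.30, adjusted p = 0.0315), Ocln (-0.96 ± 0.20) and Kitl (-0.99 ± 0.18). In the barrier list of 32 genes, 2 had a positive interaction, 12 a negative one and 18 did not pass (2 and 16 adjusted over the list alone). Its median was -0.35 (camera adjusted p = 1.90e-04, adjusted p = 0.474 with an estimated correlation). In the Sertoli list of 28 genes, 0 had a positive interaction, 8 a negative one and 20 did not pass (0 and 13 adjusted over the list alone). Its median was -0.42 (camera adjusted p = 8.13e-06, adjusted p = 0.474 with an estimated correlation). In RNA of whole testis, changes within a cell type and changed shares of cell types are not parted here either. Over all genes 1375 interactions were positive and 1359 negative. With array set as a block 3292 pass, with array weights 4904, in the first set 4002 and without the Spink8 arrays 1026. The calls of Amh and Thra end without the Spink8 arrays (adjusted p = 0.187 and 0.0761) and with quantile normalization (-0.96, adjusted p = 0.0732 and -0.94, adjusted p = 0.0578). Without a single array the count is 1692 (unexposed homozygous 1), 1563 or 1819 (unexposed wild type 1 or 3) or 1799 (exposed wild type 2).

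With the heterozygous genotype 74 interactions were positive and 1 negative at day 15. Cmtm2b, of the chemokine-like family (3.04 ± 0.44), the sperm gene Ccdc38 (2.91 ± 0.47, adjusted p = 0.0103) and Adam3 (2.73 ± 0.58, adjusted p = 0.0459) were positive and the ubiquitin ligase gene Mid1 negative (-1.09 ± 0.23, adjusted p = 0.0459). Among 26 pachytene genes 3 had a positive interaction, 0 a negative one and 23 did not pass (6 and 0 adjusted over the list alone). Their median was 0.69 (camera adjusted p = 2.99e-07, adjusted p = 0.87 with an estimated correlation). Blocked by array set 60 pass, with array weights 652, and in a fit on these groups alone 31. The calls of Adam3 and Mid1 depend on settings. Adam3 has adjusted p = 0.0502 without the filter, 0.0532 with the filter at the median, 0.0852 blocked by array set, 0.103 without the Spink8 arrays and 0.129 on these groups alone. Mid1 has adjusted p = 0.0502 without the filter, 0.0631 with quantile normalization, 0.0556 blocked by array set and 0.223 without the Spink8 arrays. In the first set limma calls 0, with 937 at unadjusted p under 0.05. Leaving out unexposed heterozygous array 2 or 3 gives 27 or 39, and exposed heterozygous array 1, 2 or 3 gives 43, 122 or 22. Leaving out unexposed wild type array 1 or 3 gives 26 or 31, and exposed wild type array 1, 2 or 3 gives 150, 24 or 23.

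**Figure D2:**
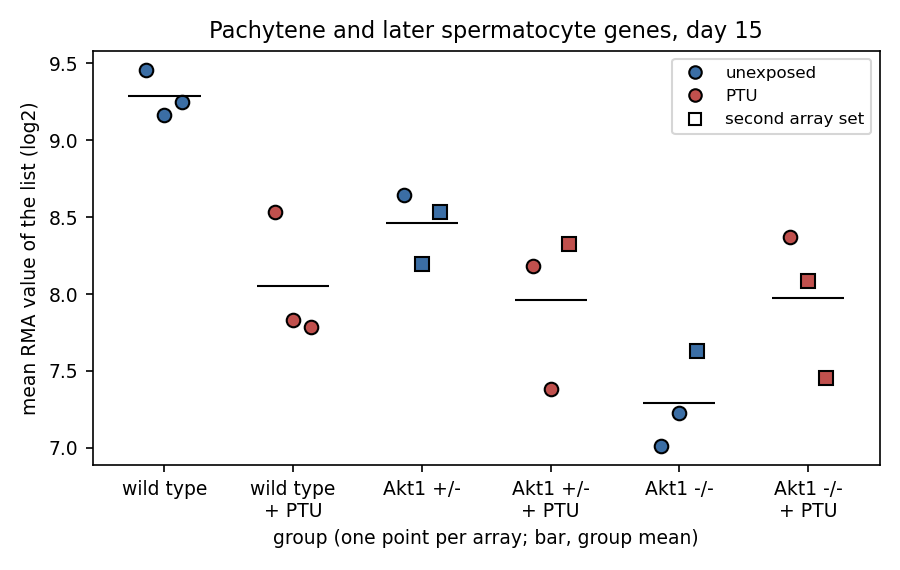
Mean RMA value (log2) of 26 pachytene and later spermatocyte genes in each day 15 array, by genotype and exposure, with squares for the second array set and bars for group means. Group means fall from 9.29 to 8.05 with PTU in wild type and lie at 7.29 and 7.97 in unexposed and exposed homozygous mice.

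At day 25 PTU in wild type testis changed 0 genes by limma, with 978 at unadjusted p under 0.05. The smallest p belonged to the chemokine receptor Ackr3 (0.63 ± 0.10, adjusted p = 0.3), the zinc finger gene Zfp932 (-0.70 ± 0.14, adjusted p = 0.738) and the muscle cofactor Fhl2 (0.51 ± 0.11, adjusted p = 0.738), none past the threshold. The protamine gene Prm1 gave -1.05 ± 0.82, adjusted p = 0.94 and Thra gave 0.19 ± 0.12, adjusted p = 0.904. Of 27 spermatid genes 0 rose, 0 fell and 27 did not pass (0 and 0 adjusted over the list alone). Their median was -0.31 (camera adjusted p = 0.0109, adjusted p = 0.798 with an estimated correlation). Of 8 adipose genes 0 rose, 0 fell and 8 did not pass (5 and 0 adjusted over the list alone). Their median was 0.84 (camera adjusted p = 0.00104, adjusted p = 0.416 with an estimated correlation). Fabp4, a fat cell transcript, reads 8.95 and 10.4 in exposed wild type arrays 2 and 3. Array weights give 6 genes, with Ackr3 and Zfp932 at adjusted p = 0.0138, and a fit on these 2 groups alone 1.

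In heterozygous testis at day 25 PTU lowered the genes that pack sperm chromatin. Prm1 (-3.95 ± 0.82), Prm2 (-4.18 ± 0.79), Tnp1 (-3.61 ± 0.74) and Tnp2 (-4.32 ± 0.86) fell. Among 27 spermatid genes 0 rose, 22 fell and 5 did not pass (0 and 22 adjusted over the list alone). Their median was -1.48 (camera adjusted p = 2.43e-16, adjusted p = 0.518 with an estimated correlation). Inhbb, an inhibin subunit of Sertoli cells, rose (0.64 ± 0.14). Of 26 Sertoli genes 13 rose, 0 fell and 13 did not pass (17 and 0 adjusted over the list alone). Their median was 0.37 (camera adjusted p = 3.32e-06, adjusted p = 0.518 with an estimated correlation). The gap junction gene Gja1 (0.55 ± 0.10) and the tight junction genes Cldn11 (0.56 ± 0.13) and Tjp1 (0.28 ± 0.09, adjusted p = 0.0365) rose. Of 33 barrier genes 9 rose, 0 fell and 24 did not pass (12 and 0 adjusted over the list alone). Their median was 0.28 (camera adjusted p = 0.00117, adjusted p = 0.518 with an estimated correlation). The germ cell gene Dazl (0.46 ± 0.09) and the cyclin Ccnd1 (0.66 ± 0.11) rose. Among 22 spermatogonia genes 9 rose, 0 fell and 13 did not pass (13 and 0 adjusted over the list alone). Their median was 0.38 (camera adjusted p = 3.58e-04, adjusted p = 0.518 with an estimated correlation). Of 25 cell cycle genes 10 rose, 0 fell and 15 did not pass (11 and 0 adjusted over the list alone). Their median was 0.24 (camera adjusted p = 0.00305, adjusted p = 0.518 with an estimated correlation). Over all 16305 genes 1868 rose and 1174 fell. With the level of the poly-A labelling controls as a covariate 1220 pass, and Tjp1 does not (0.21, adjusted p = 0.159). Tjp1 also fails without the Spink8 arrays (0.25, adjusted p = 0.0911) and on these groups alone (adjusted p = 0.0666). With the sample number as a replicate block it has adjusted p = 0.0534, though the numbers do not pair the samples here. Without unexposed array 2, unexposed array 3 or exposed array 2 the count is 874, 1668 or 956. Exposed array 2 also reads high for the epididymal Spink8 (10.1) and has the fat cell transcript Fabp4 at 7.63, the source of which was not tested. Its spermatid list mean is 9.34, against 10.2 and 10.5 in the other exposed arrays, and without it the list median is -1.18.

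In homozygous testis at day 25 PTU lowered spermatid transcripts. Tnp1 (-7.64 ± 0.83), Prm1 (-6.55 ± 0.92), the sperm fusion gene Izumo1 (-4.47 ± 0.31) and the sperm tail gene Odf1 (-6.47 ± 0.59) fell, with 2 exposed and 3 unexposed arrays. In the spermatid list of 27 genes, 0 rose, 26 fell and 1 did not pass (0 and 26 adjusted over the list alone). Its median was -4.60 (camera adjusted p = 2.34e-11, adjusted p = 0.449 with an estimated correlation). The axoneme gene Spag6 fell (-4.92 ± 0.43). In the pachytene list of 26 genes, 1 rose, 21 fell and 4 did not pass (1 and 21 adjusted over the list alone). Its median was -1.20 (camera adjusted p = 5.11e-05, adjusted p = 0.449 with an estimated correlation). Rhox13, of earlier germ cells (1.95 ± 0.18), rose, as did Dmrt1, made by Sertoli cells and spermatogonia (1.47 ± 0.15). In the spermatogonia list of 22 genes, 21 rose, 0 fell and 1 did not pass (21 and 0 adjusted over the list alone). Its median was 1.23 (camera adjusted p = 8.38e-06, adjusted p = 0.449 with an estimated correlation). Stra8, which starts meiosis (1.49 ± 0.18), and Tex11 (1.96 ± 0.12) rose, and the cohesin gene Rec8 fell (-1.95 ± 0.18). In the early meiotic list of 24 genes, 15 rose, 4 fell and 5 did not pass (15 and 4 adjusted over the list alone). Its median was 0.58 (camera adjusted p = 0.0466, adjusted p = 0.497 with an estimated correlation).

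**Figure D3:**
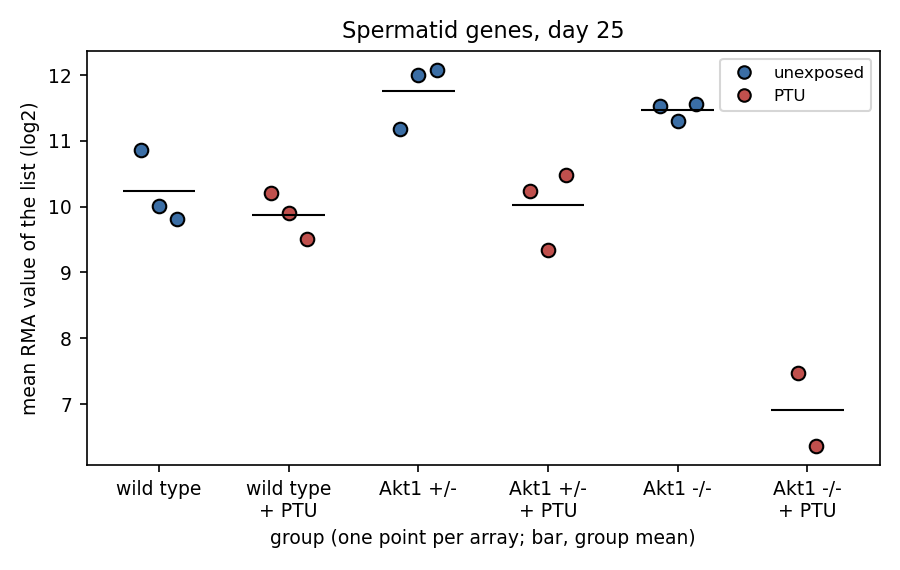
Mean RMA value (log2) of 27 spermatid genes in each day 25 array, by genotype and exposure, with bars for group means. Exposed homozygous arrays average 6.92, against 11.5 in unexposed homozygous and 9.88 in exposed wild type arrays.

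Somatic genes moved in the same exposed homozygous testes, whose arrays also carry the epididymal transcripts given below. Whether RNA of that tissue adds to the rises of Sertoli and junction genes was not tested. Thra (1.96 ± 0.14), the keratin Krt18 (4.79 ± 0.36) and Ccnd2 (1.51 ± 0.13), markers of immature Sertoli cells, rose. Of 12 immature Sertoli genes 9 rose, 1 fell and 2 did not pass (10 and 1 adjusted over the list alone). Their median was 1.31 (camera adjusted p = 0.00561, adjusted p = 0.449 with an estimated correlation). The junction genes F11r (1.41 ± 0.12), Ocln (1.23 ± 0.19), Tjp1 (0.76 ± 0.10) and Gja1 (1.01 ± 0.12) rose. Among 33 barrier genes 23 rose, 1 fell and 9 did not pass (23 and 2 adjusted over the list alone). Their median was 0.66 (camera adjusted p = 0.00165, adjusted p = 0.449 with an estimated correlation). Among 26 Sertoli genes 20 rose, 3 fell and 3 did not pass (20 and 3 adjusted over the list alone). Their median was 0.66 (camera adjusted p = 0.00486, adjusted p = 0.449 with an estimated correlation). The steroid enzymes Cyp11a1 (-4.67 ± 0.51) and Cyp17a1 (-4.74 ± 0.89) fell, Akr1c14 rose (2.55 ± 0.27) and Rhox5, an androgen target, fell (-1.52 ± 0.39). Among 15 Leydig genes 5 rose, 4 fell and 6 did not pass (5 and 4 adjusted over the list alone). Their median was 0.04 (camera adjusted p = 0.94, adjusted p = 0.974 with an estimated correlation). The Leydig mean was -0.20 while camera's direction was up. Of 6 erythroid genes 0 rose, 6 fell and 0 did not pass (0 and 6 adjusted over the list alone). Their median was -0.70 (camera adjusted p = 0.034, adjusted p = 0.449 with an estimated correlation). With the poly-A controls as a covariate Cyp17a1 (-3.94, adjusted p = 0.116) and Tjp1 (0.46, adjusted p = 0.0591) no longer pass, and Rhox5 turns positive (0.25, adjusted p = 0.771).

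Transcripts known from epididymis and fat came with these changes, and their source was not tested. The epididymal genes Defb42 (7.49 ± 0.84), Spink8 (6.83 ± 0.95) and Adam7 (4.03 ± 0.49) and the fat cell gene Fabp4 (4.34 ± 1.06) rose, Fabp4 not passing with array weights (adjusted p = 0.113) or the poly-A covariate (3.48, adjusted p = 0.24). Spink8 reads 12.9 and 12.8 in the exposed homozygous arrays, 10.1 in exposed heterozygous array 2, 8.72 in exposed wild type array 3 and at most 6.40 elsewhere. Poly-A controls average 8.95 in exposed homozygous, 8.18 in exposed wild type and 6.63 in unexposed homozygous arrays. The 18S probes read 10.8 in exposed homozygous array 2 against 7.44 at most in unexposed arrays. The 3' minus 5' difference of beta-actin, a sign of RNA quality, is 1.26 in exposed and 1.09 in unexposed homozygous arrays, 0.59 in unexposed wild type and 0.66 in unexposed heterozygous arrays. Over all genes 6264 rose and 5351 fell, and 4107 pass with the poly-A covariate. Averaged over genotypes 5919 rose and 4504 fell. The tight junction gene Cldn1 (1.37 ± 0.09) and Dlk1 (1.44 ± 0.19) rose and Tbata, of spermatids, fell (-1.48 ± 0.12). Without the exposed homozygous arrays this count is 2855, and with the covariate 3018, Dlk1 not passing (0.78, adjusted p = 0.0722).

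Unexposed homozygous testes at day 25 had more spermatid transcript than wild type. Prm1 (3.19 ± 0.82, adjusted p = 0.0251), Tnp1 (2.78 ± 0.74, adjusted p = 0.0279) and the kinase gene Tssk6 (2.41 ± 0.49, adjusted p = 0.0131) were higher. Of 27 spermatid genes 9 were higher, 0 lower and 18 did not pass (19 and 0 adjusted over the list alone). Their median was 1.01 (camera adjusted p = 4.87e-10, adjusted p = 0.716 with an estimated correlation). The filament gene Vim (-0.68 ± 0.12) and Dmrt1, a gene of Sertoli cells and spermatogonia (-0.53 ± 0.13, adjusted p = 0.0231), were lower. In the Sertoli list of 26 genes, 0 were higher, 6 lower and 20 did not pass (0 and 10 adjusted over the list alone). Its median was -0.28 (camera adjusted p = 6.20e-05, adjusted p = 0.671 with an estimated correlation). The lipid enzyme Agpat1 (-1.15 ± 0.10) and the actin binder Pfn1 (-1.20 ± 0.17) were lower. Over all genes 872 were higher and 1193 lower. The poly-A controls average 7.80 (7.66 to 7.99) in these wild type and 6.63 (6.11 to 7.03) in these homozygous arrays, without overlap. As a covariate they leave 180 genes, with Agpat1 (-1.19) past the threshold and Prm1 (2.79, adjusted p = 0.215), Tnp1 (2.66, adjusted p = 0.200), Tssk6 (2.64, adjusted p = 0.0845), Vim (-0.54, adjusted p = 0.105) and Dmrt1 (-0.21, adjusted p = 0.421) not. The spermatid median is then 0.26. Labelling level and genotype cannot be told apart in these arrays. RNA quality differs as well: the beta-actin difference is 0.953 to 1.31 in these homozygous and 0.546 to 0.673 in these wild type arrays. With it as a covariate 598 genes pass. Without the exposed homozygous arrays or without every Spink8 array the count is 3388 or 3195. Array weights give 4871, and every probe set on its own 3356. Leaving out homozygous array 1 or 3 gives 987 or 315, and wild type array 1, 2 or 3 gives 1054, 1269 or 84.

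Between exposed homozygous and wild type testes at day 25, 5334 genes were higher and 4625 lower, in arrays that carry the epididymal transcripts. Izumo1 (-3.15 ± 0.31) and Cyp11a1 (-4.49 ± 0.51) were lower. Among 27 spermatid genes 0 were higher, 24 lower and 3 did not pass (0 and 25 adjusted over the list alone). Their median was -3.15 (camera adjusted p = 1.26e-09, adjusted p = 0.473 with an estimated correlation). Averaged over exposure 3352 were higher and 3558 lower, with Agpat1 (-1.38 ± 0.08) and Cyp11a1 (-2.59 ± 0.34) lower.

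Averaged over exposure, heterozygous testes at day 25 also had more spermatid transcript than wild type. The list means are 11.8 against 10.2 in unexposed mice, while exposed heterozygous arrays range from 9.34 to 10.5 around an exposed wild type mean of 9.88. Prm1 (2.28 ± 0.58, adjusted p = 0.016) and the sperm gene Tex44 (1.11 ± 0.22) were higher and the interferon gene Ifi27l2a lower (-1.09 ± 0.21). In the spermatid list of 27 genes, 11 were higher, 0 lower and 16 did not pass (12 and 0 adjusted over the list alone). Its median was 0.63 (camera adjusted p = 5.62e-07, adjusted p = 0.792 with an estimated correlation). Of 26 Sertoli genes 0 were higher, 10 lower and 16 did not pass (0 and 15 adjusted over the list alone). Their median was -0.22 (camera adjusted p = 1.46e-05, adjusted p = 0.792 with an estimated correlation). Over all genes 1088 were higher and 1982 lower, and with the poly-A covariate 2 pass, without Prm1 (1.91, adjusted p = 0.333), Tex44 (1.10, adjusted p = 0.178) and Ifi27l2a (adjusted p = 0.191). The poly-A controls read 6.29 to 7.60 in heterozygous and 7.66 to 8.47 in wild type arrays. Labelling level and genotype thus cannot be told apart here either. The count is 5609 with array weights, 1769 without unexposed heterozygous array 2, 1836 without exposed heterozygous array 3, 1666 without unexposed wild type array 3 and 1639 without exposed wild type array 3.

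The interaction of PTU with the homozygous genotype at day 25 was negative for Tnp1 (-6.96 ± 1.12), Prm1 (-5.50 ± 1.23) and Cyp17a1 (-3.55 ± 1.20, adjusted p = 0.0191). It was positive for Thra (1.78 ± 0.18), Ocln (1.12 ± 0.26) and Stra8 (1.41 ± 0.24). Of 27 spermatid genes 0 had a positive interaction, 26 a negative one and 1 did not pass (0 and 26 adjusted over the list alone). Their median was -4.48 (camera adjusted p = 7.68e-12, adjusted p = 0.4 with an estimated correlation). Of 22 spermatogonia genes 20 had a positive interaction, 0 a negative one and 2 did not pass (20 and 0 adjusted over the list alone). Their median was 1.12 (camera adjusted p = 8.79e-06, adjusted p = 0.4 with an estimated correlation). Over all genes 5396 were positive and 4288 negative. With the poly-A covariate 4123 pass, but not Prm1 (-4.84, adjusted p = 0.0642) or Cyp17a1 (-2.89, adjusted p = 0.237). Cyp17a1 also fails with array weights (-3.73, adjusted p = 0.105). With the heterozygous genotype limma called 0 genes, with 2982 at unadjusted p under 0.05. The smallest p belonged to the GTPase gene Rhob (0.72 ± 0.13, adjusted p = 0.139), the transferase gene B3gnt8 (0.65 ± 0.11, adjusted p = 0.139) and Wipf3 (0.71 ± 0.13, adjusted p = 0.139), none past the threshold. Among 27 spermatid genes 0 had a positive interaction, 0 a negative one and 27 did not pass (0 and 6 adjusted over the list alone). Their median was -1.27 (camera adjusted p = 2.99e-12, adjusted p = 0.409 with an estimated correlation). Leaving out unexposed heterozygous array 1 gives 945 genes, exposed heterozygous array 1 gives 1, and array weights give 2003, with these 3 at adjusted p = 0.0257.

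**Figure D4:**
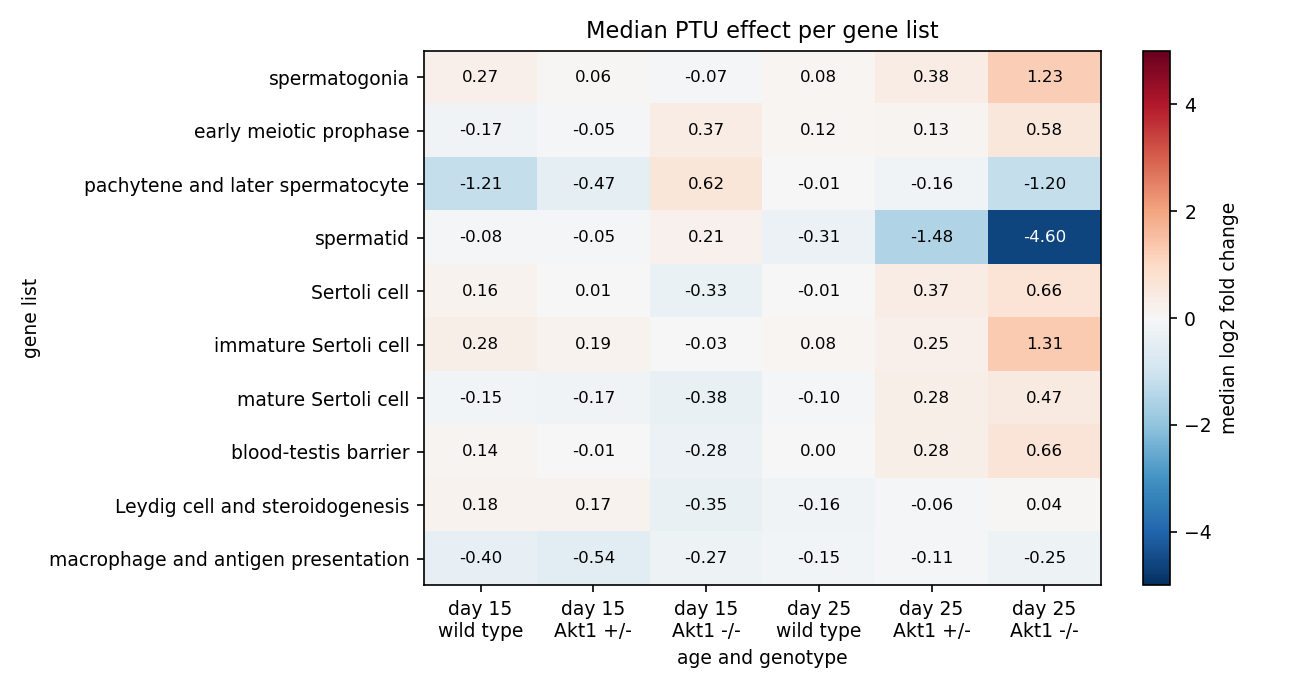
Median log2 fold change under PTU of 10 gene lists (y axis) by age and Akt1 genotype (x axis), colour and number giving the median. The spermatid list at day 25 goes from -0.31 in wild type to -1.48 in heterozygous and -4.60 in homozygous mice, and the pachytene list at day 15 from -1.21 to -0.47 and 0.62.

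Genes shared between genotypes and ages were counted last. At day 15, 70 genes such as Tsx, Bbox1 and Hsd17b3 changed alike in wild type and heterozygous mice. They comprise 26 rises, against 2.09 if the lists were independent, and 44 falls, against 5.51, with 0 genes changed in opposite directions. Across genes the wild type and heterozygous effects correlate at r = 0.691 and the wild type and homozygous effects at r = -0.352, and genes are not independent replicates. Between wild type and homozygous mice 4 rises were shared against 6.40 and 79 falls against 63.9, while 57 genes changed in opposite directions. At day 25 heterozygous and homozygous effects correlate across genes at r = 0.809, with 1749 shared rises against 717.6 and 1088 shared falls against 385.3. Between the ages the averaged PTU effects of 14281 genes correlate at r = 0.269 (Spearman 0.309). This averaged r is 0.397 with a filter at the median and 0.128 without the exposed homozygous arrays of day 25. In all, 389 genes such as Thra and Akr1c14 rose at both ages and 581 fell at both, against 219.7 and 311.6, while 47 rose at day 15 and fell at day 25 and 260 did the reverse. Within homozygous mice the PTU effects of the ages correlate across genes at r = -0.242. The interactions of PTU with the homozygous genotype correlate between the ages at r = -0.438. Only 48 were positive and 66 negative at both ages, against 445.4 and 302.0 if independent. Another 912 were positive at day 15 and negative at day 25, and 913 the reverse. Camera with its preset correlation made 136 calls in 500 list tests, of which 0 hold with an estimated correlation, so every list call here rests on the preset. Fry, which tests whether a set moves on balance one way, called 165.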

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

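In this part the tests of dilution, of a lower spermatid share alone and of exchanged labels, the error of the list mean and the look at beta-actin array by array, and the array set and Spink8 settings, were chosen after seeing the data. A test of whether the PTU effect differs between genotypes picked out these results. At day 15 the interaction with the homozygous genotype passed for 2734 genes and with the heterozygous genotype for 75, and at day 25 with the homozygous genotype for 9684. At day 15 the pachytene and later spermatocyte list has an interaction median of 2.04, and of the fixed markers Amh (-1.07) and Thra (-1.01) passed, but neither does with quantile normalization (adjusted p = 0.0732 and 0.0578) or without the Spink8 arrays (adjusted p = 0.187 and 0.0761). At day 25 the medians are 1.25 for immature Sertoli cell, 1.12 for spermatogonia, -1.18 for pachytene and later spermatocyte and -4.48 for spermatid, and the markers that passed with a change of more than 1 log2 are Tnp1 (-6.96), Prm1 (-5.50), Cyp17a1 (-3.55), Stra8 (1.41), Ocln (1.12) and Thra (1.78).

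A look at signals outside the gene measurement picked out arrays that exceed every unexposed array of day 25. The mean of the poly-A labelling controls is 8.25 and 9.64 in exposed homozygous arrays 1 and 2 and 8.21 and 8.47 in exposed wild type arrays 1 and 3, against 7.99 at most in unexposed arrays. The 18S probes read 10.8 in exposed homozygous array 2, against 7.44 at most. The beta-actin difference is 1.44 in that array, against 1.31 at most.

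Spermatid transcripts are low in exposed homozygous testes at day 25, where dilution by epididymal RNA would lower all germ cell genes alike, but the early meiotic median is 0.58, and the spermatid minus early meiotic list mean is -4.77 and -3.69 in these arrays against -1.51 to 1.40 in the other 15. With the beta-actin difference as a covariate the spermatid median is -4.37, and the change of the list mean is -4.39 ± 0.51, which argues against a linear trend with RNA quality so measured as the whole cause. Of the exposed homozygous arrays, array 1 (1.08, spermatid mean 7.48) lies among the unexposed ones in that difference (0.953 to 1.31, means 11.3 to 11.6), and array 2 (1.44, 6.36) lies above them, so a part played by RNA quality stays open. A lower spermatid share alone would raise spermatogonial and macrophage genes alike, but the spermatogonia list rose by 1.33 ± 0.18 more than the macrophage list. The macrophage list mean went from 7.50 to 7.39. PTU lowered macrophage genes at day 15, so a macrophage change of its own could give this difference. A lower spermatid share as a part of the cause thus stays open. The hypothesis that PTU and loss of Akt1 together halt germ cells before the spermatid stage, and the hypothesis of a delayed litter, could both hold and were not tested.

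The second pattern is the pachytene interaction at day 15. The interaction median is 2.01 with array set as a block, which argues against array set as the whole cause; it is 2.72 within the first set, where exposed homozygous mice have 1 array. If the exposed and unexposed homozygous labels were exchanged, genes that PTU changes alike in wild type and heterozygous mice would go the other way. Of these, 85.7% (60 of 70) go the same way, with 28 past the threshold that way and 0 the opposite way. Over all genes called in both wild type and homozygous mice, 4 rise in both, 79 fall in both and 57 go opposite ways. A lag of unexposed homozygous mice in meiosis, leaving less for PTU to lower, would give a smaller fall. The median change of the pachytene list in homozygous mice is 0.62 (0.41 to 0.90 with 1 homozygous array left out, 0.10 in the second set). None of its genes rose past the threshold, and list means by array overlap (7.01 to 7.63 unexposed, 7.46 to 8.37 exposed). A rise is thus not established, and a lag stays open. At day 25 no lag shows: the spermatid list mean is 11.5 in unexposed homozygous and 10.2 in unexposed wild type mice. Those are other mice, in which labelling level and RNA quality differ along with genotype. Litters differing by a day of development could also give the pattern of day 15. Neither the lag nor the litters were tested further.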

How the results depend on the processing

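The array set, poly-A, Spink8 and exposed homozygous settings were chosen after seeing the data. Leaving out each array in turn gives these lowest and highest counts of genes at day 15: PTU averaged 1278 to 2923, in wild type 1116 to 2687, in heterozygous 3 to 414, in homozygous 56 to 1598; homozygous minus wild type averaged 2633 to 6737, unexposed 3055 to 4521, exposed 0 to 3308; heterozygous minus wild type 44 to 452; interaction with homozygous 1563 to 3130 and with heterozygous 22 to 150. At day 25 they are: PTU averaged 9497 to 11148, in wild type 0 to 0 by limma (518 to 913 at unadjusted p under 0.05), in heterozygous 874 to 3618, in homozygous 9613 to 11818; homozygous minus wild type averaged 4636 to 8281, unexposed 84 to 1588, exposed 7241 to 10428; heterozygous minus wild type 1639 to 3518; interaction with homozygous 7910 to 10549 and with heterozygous 0 to 945. The correlation of PTU effects between the ages ranges from 0.206 to 0.315, with a jackknife error of 0.112. Where 1 exposed homozygous array of day 25 is left out, its group has 1 sample; limma pools the spread over groups, and the lone sample is assumed to vary like the others. The cause of these ranges was not tested.

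Array weights raised these counts. At day 15 they give 3650 for PTU averaged, 6820 in wild type, 499 in heterozygous, 1550 in homozygous, 7404 for homozygous minus wild type unexposed and 1187 exposed, 1257 for heterozygous minus wild type, and 4904 and 652 for the homozygous and heterozygous interactions. At day 25 they give 6 for PTU in wild type, 4871 for homozygous minus wild type unexposed, 5609 for heterozygous minus wild type and 2003 for the heterozygous interaction. The cause was not tested.

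The day 15 array set, as a block, moves homozygous minus wild type averaged to 2991 and heterozygous minus wild type to 34. Within the first set the counts are 1028 for PTU averaged, 4389 in wild type, 1 in heterozygous and 1522 for homozygous minus wild type averaged. There limma calls 0 for PTU in homozygous (3993 at unadjusted p under 0.05), 0 for heterozygous minus wild type (1742) and 0 for the heterozygous interaction (937); within the second set they are 3 for PTU in heterozygous and 4 in homozygous. Without the arrays that carry Spink8, day 15 gives 846 for PTU averaged, 831 in wild type, 48 in heterozygous, 0 in homozygous (2270 unadjusted), 1719 for homozygous minus wild type averaged, 2476 unexposed, 93 for heterozygous minus wild type and 1026 for the homozygous interaction, and day 25 gives 3195 for homozygous minus wild type unexposed. A fit on the groups compared alone gives 4370 for PTU in wild type, 31 in heterozygous, 0 in homozygous (2695 unadjusted) and 31 for the heterozygous interaction at day 15, and 1 for PTU in wild type at day 25. Smaller subsets have fewer arrays to estimate the spread, which was not separated from the arrays themselves.

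Quantile normalization moves homozygous minus wild type exposed at day 15 from 0 to 123, and every probe set on its own moves homozygous minus wild type unexposed at day 25 to 3356. Without the exposed homozygous arrays day 25 gives 2855 for PTU averaged and 3388 for homozygous minus wild type unexposed, and the correlation between the ages is 0.128. With the poly-A control mean as a covariate day 25 gives 3018 for PTU averaged, 1220 in heterozygous, 4107 in homozygous, 180 for homozygous minus wild type unexposed, 2 for heterozygous minus wild type and 4123 for the homozygous interaction. The filter at the median moves the correlation between the ages to 0.397. With an estimated correlation camera calls 0 of 500 list tests, the lowest adjusted p being 0.078. Of the Akt1 probe sets at day 25 a second one gives -0.79 (adjusted p = 3.82e-04). The cause was not tested in any of these.

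With the sample number as a replicate block, day 15 gives 750 for homozygous minus wild type exposed, where the numbers pair the samples by the residual rule. That rule and the block use the same values, so pairing is not established. Exposed homozygous array 3 and exposed wild type array 2 correlate at 0.377 there, above the 0.141 of both arrays numbered 2. In the other comparisons whose numbers pair, PTU in heterozygous at day 15 and in wild type at day 25, the block moves no count by over 1.5 times, and it changed no call of a list in any of these. Elsewhere the samples share only a number, and the block gives 767 for heterozygous minus wild type and 130 for the heterozygous interaction at day 15. Residuals of arrays that share a number correlate at a median of 0.101 at day 15 and 0.00179 at day 25, against -0.105 and -0.0186 for arrays that do not, a hint from the data and not from the design. Of 167 gene values 163 kept direction and side of the threshold with the replicate block.

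Of 167 gene values in the text, 158 kept direction and side of the threshold with quantile normalization, 164 without the filter and 155 with array weights, and 163 of the 164 left by the filter at the median. A call was lost in 18 of the fits on the groups compared alone, 34 in the first array set, 20 in the second, 7 with array set as a block, 27 without the Spink8 arrays, and 146 of the fits with 1 array left out, against 10 gained. With the poly-A covariate 15 calls were lost and 1 turned: Rhox5 under PTU in homozygous mice at day 25 goes to 0.25 (adjusted p = 0.771). Every probe set on its own was not run for single genes. The number of arrays limits what these comparisons resolve.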

Other observations

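Of the tests in this part the poly-A and beta-actin covariates, the Spink8 and array set settings, leaving out 2 arrays at once and the splits by pairs were chosen after seeing the data. Further gene groups moved in the exposed homozygous testes of day 25. The immediate early and heat shock list mean went from 7.69 to 8.46 with PTU. It was 8.25 and 8.67 by exposed array, against 8.09 at most in other groups of that age. Whether stress bears on the other changes in the exposed homozygous arrays was not tested. In these arrays transcripts known from other tissue are high, and their source was not tested: from unexposed to exposed the epididymis list mean goes from 5.32 to 7.57 and the adipose one from 5.96 to 7.24, and Spink8 reads 12.9 and 12.8. Most targets of FoxO, the transcription factors that Akt restrains, rose with PTU. Of 17 FoxO target genes 12 rose, 2 fell and 3 did not pass (12 and 2 adjusted over the list alone). Their median was 0.97 (camera adjusted p = 0.0448, adjusted p = 0.449 with an estimated correlation). Genotype without PTU showed no such rise: their list mean at day 25 was 8.12 in unexposed homozygous and 8.29 in unexposed wild type testes. In homozygous mice of day 15 it went from 8.94 to 8.78 with PTU. In heterozygous mice of day 25 it went from 8.11 to 8.31. The rise in homozygous mice of day 25 (8.12 to 8.80) is not particular to FoxO targets. Means rose more for spermatogonia (8.13 to 9.35) and immature Sertoli cells (8.37 to 9.60), while the macrophage mean fell (7.50 to 7.39). A changed share of cell types is not parted from a change within cells. With PTU in homozygous testes of day 25, genes of the peritubular myoid cells that wrap the tubules moved too. Of 15 peritubular myoid genes 12 rose, 1 fell and 2 did not pass (12 and 1 adjusted over the list alone). Their median was 1.23 (camera adjusted p = 0.00165, adjusted p = 0.449 with an estimated correlation). Of 19 apoptosis genes 11 rose, 4 fell and 4 did not pass (11 and 4 adjusted over the list alone). Their median was 0.55 (camera adjusted p = 0.142, adjusted p = 0.465 with an estimated correlation). Of 19 macrophage genes 2 rose, 6 fell and 11 did not pass (2 and 5 adjusted over the list alone). Their median was -0.25 (camera adjusted p = 0.284, adjusted p = 0.737 with an estimated correlation).

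At day 15 the imprinted gene Dlk1 (1.72 ± 0.21) and Sel1l3 (2.66 ± 0.25) were higher in unexposed homozygous than in unexposed wild type testes. In homozygous testes PTU lowered Bcl2l11, a FoxO target that drives cell death (-0.62 ± 0.11), and the growth factor gene Igf1 (-0.73 ± 0.17, adjusted p = 0.0209). Neither passes in a fit on these groups alone (adjusted p = 0.105 and 0.117), without the Spink8 arrays (adjusted p = 0.114 and 0.178), in the first array set (adjusted p = 0.0821 and 0.149) or in the second (adjusted p = 0.339 and 0.318).

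Spermatid transcripts are higher in unexposed homozygous than wild type testes at day 25. With the poly-A control mean as a covariate the spermatid median goes from 1.01 to 0.26, and Prm1 from 3.19 to 2.79 with adjusted p = 0.215. A labelling difference thus stays open, though spike levels may also depend on the share of mRNA in the sample, which was not tested. These controls part the groups without overlap (6.11 to 7.03 in homozygous, 7.66 to 7.99 in wild type). Labelling level and genotype thus cannot be told apart. The beta-actin difference parts the groups without overlap (0.953 to 1.31 in homozygous, 0.546 to 0.673 in wild type), so RNA quality and genotype cannot be told apart here; as a covariate it gives a median of 1.83 and a list mean difference of 1.69 ± 0.73, too wide an error to decide. No single array accounts for the median, which is 0.83 to 1.21 with 1 left out and at least 0.68 with any 2 left out, but without wild type array 3 the gene count goes from 2065 to 84. A genotype effect or an older litter could also give it, and neither was tested.

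Splits ask how often other groupings of the same arrays call as many genes. At day 15 the real count of PTU averaged (2001) was reached by 3 of 100 splits (highest other 2391), homozygous minus wild type averaged (4721) by 3 of 100 (5368), heterozygous minus wild type (167) by 4 of 100 (481) and the homozygous interaction (2734) by 1 of 100 (1140), which is the real grouping itself. The share is under 0.05 in each, without adjustment for the number of contrasts split, and for the first 3 some other splits exceed the real count. For PTU averaged and homozygous minus wild type averaged this unadjusted share argues only weakly against chance alone. The split that gives 5368 exchanges all unexposed labels, so it keeps the whole unexposed difference with its sign turned. The split that gives 2391 keeps every wild type label. Both counts can thus hold real differences. Splits of an interaction exchange exposure labels within a genotype, so they ask whether PTU acts at all. They cannot decide whether the homozygous interaction arises by chance. For heterozygous minus wild type the share lies near the limit, with 100 splits drawn of 200, and 481 is several times the real count, which leaves that count open. The split that gives 481 keeps every unexposed label, so it still holds the real unexposed difference. The heterozygous interaction (75) was reached by 9 of 100, so chance is not excluded. The highest other count, 3079, comes from a split that exchanges all wild type exposure labels and those of 1 array in each heterozygous group. Such a split keeps the whole wild type PTU difference (2553 genes) with its sign turned, so its count can come from that difference. At day 25 heterozygous minus wild type (3070) was reached by 1 of 100 (1688), the real grouping itself, which argues against chance alone. The heterozygous interaction (0) was reached by 100 of 100 (2077), so a count of 0 carries no call.

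With 3 arrays in each of 2 groups there are 10 splits, too few for a share under 0.05. At day 15 the real count and the highest other are 2553 and 0 for PTU in wild type (1 of 10), 95 and 1 in heterozygous (1 of 10), 828 and 3 in homozygous (1 of 10), 4821 and 0 for homozygous minus wild type unexposed (1 of 10) and 0 and 0 exposed (10 of 10). At day 25 they are 0 and 0 for PTU in wild type (10 of 10), 3042 and 0 in heterozygous (1 of 10) and 2065 and 0 for homozygous minus wild type unexposed (1 of 10). Where the sample numbers pair the arrays (PTU in heterozygous and homozygous minus wild type exposed at day 15, PTU in wild type at day 25), 3 other splits part as many pairs and give at most 0. The rest part fewer and give at most 1. Contrasts with the exposed homozygous arrays of day 25 were not split, since that group has 2 arrays.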
